A study of Rattus norvegicus with 12 samples.

How the data were processed

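Total RNA from epididymal white adipose tissue was hybridised to Affymetrix rat arrays, 1 array per sample, 12 arrays in all. The labels give 3 groups of 4: rats fed ad libitum (AL), rats under caloric restriction (CR), and rats heterozygous for an antisense growth hormone transgene and fed ad libitum (Tg). The samples are labelled as separate biological replicates. Groups were taken from the titles and source names, since the genotype field reads Wistar (-/-), the labels' term for rats without the transgene, on all 12 arrays, the Tg arrays included. The sample descriptions carry a code that is shared within each group and differs between groups. If that code marks a working session, batch and group cannot be told apart.

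Each array's deposited file holds a score, a z-score for every perfect-match probe, with 11 probes in 31061 of the 31099 probe sets and 342410 probes in all. A second deposited table gives each array's background, mean and SD on the log10 scale, per the file headers. It also gives a saturation level for each array, which 0.000295% to 0.186% of the probe values exceeded. Undoing the z-score with an array's own parameters gave whole numbers, within 0.01, for 100% of the values under 5000, and with another array's parameters for 0.730% to 3.06%. The authors' z-score is therefore the log10 of the background-subtracted intensity, centred and scaled array by array. Blank probes made up 0.324% to 1.88% of 11 arrays and 5.71% of CR3. The series matrix holds a linear intensity per probe set, deposited by the authors, with column medians from 222.6 to 239.4. Its log10 lay on a line in the mean z-score of the probe set, with a mean slope of 0.693 and r from 0.987 to 0.995, and its direction is that of the brightness. The exact summary the authors used for that table, and any software behind either table, is not given in the sources used here.

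The choices of test, filter, gene lists, named genes and most other settings tried were made before the data were examined. They assumed 1 signal per probe set and array; the files held z-scores of single probes instead, so a summary step was added. Probe z-scores were summarised by median polish, leaving out blank probes, and put on a log2 signal scale with the mean SD (0.689) and mean (1.98) of the 12 arrays. Because the z-scores were already centred and scaled array by array, no further normalization was applied in the reported values. The medians were not quite equal: the median z-score was 0.069 on CR3 and -0.0045 to 0.020 on the other arrays. With each array centred on its median, 305 probe sets were called for CR against AL and 221 for CR against Tg. Signals under 1 were set to 1. The files gave no detection calls, so probe sets whose mean over the 12 arrays lay above the 25th percentile were tested, and the 57 control probe sets were left out. This left 23281 probe sets and 12096 named genes.

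Gene names came from the platform annotation provided for this work. Of the probe sets, 20826 had 1 gene symbol, 436 had several and 9780 were unnamed here; the symbols cover 14218 genes. By gene identifier, 20758 probe sets matched the RefSeq gene table of assembly GRCr8, and 0 symbols needed an update. No gene was named from a probe set with several symbols, and no coordinates are given.

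Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 1 mean per group, all 12 arrays in the fit and two-sided tests. P-values were adjusted by Benjamini-Hochberg within each comparison, and adjusted p under 0.05 counts as past the threshold. Fold changes are differences of mean log2 signal, given with the standard error (SE) of the fit; group values are mean ± SD over 4 arrays. The fixed gene lists, 30 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, on the brightest tested probe set of each gene, and again with the correlation estimated for each list. For each list the number of members past the threshold is given over all probe sets and adjusted over the list alone.

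Named genes follow a rule. For CR against AL and for Tg against AL they are the 10 genes that rose and the 10 that fell with the largest change among those past the threshold whose arrays did not overlap, represented by the brightest probe set of the gene. For CR against Tg, 5 and 5 were taken. Up to 4 members of each list in each direction were added, or, where none passed, up to 2 with the smallest p. Genes named whatever their values were Gh1, Ghr, Igf1, Socs2, Lep, Adipoq, Pparg, Srebf1, Fasn, Acly, Scd, Cd68, Ccl2, Ucp1 and Ppargc1a. Of lists without a call, only some of these genes are named. Genes outside the rule are said to have been chosen after their values were seen.

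Separation of the groups was tested on squared Euclidean distances with an exact permutation test over all partitions of the 12 arrays, and over 35 splits for each pair of groups. The correlation of the changes in CR and Tg, which share the AL arrays, was set beside 100 simulations with no effect and beside the 6 ordered ways of splitting the controls. The fit was tested on simulated data in which 200 of the 23281 probe sets were changed by known folds. For CR against AL, 55.2% of the probe sets changed 1.5-fold, 89.6% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, with 9 unchanged probe sets called. For Tg against AL the shares were 53.7%, 88.1% and 97.0%, with 5 unchanged called, and for CR against Tg 71.6%, 92.5% and 97.0%, with 13. In simulations of the list test a shifted gene list was called in each comparison, and 0 of the others. The simulations of the fit and of the lists drew every probe set independently, so they do not show how often lists of correlated genes are called with no effect. The shares recovered and the unchanged probe sets called may also differ on the real arrays, whose probe sets vary together. Splits of the real arrays that mix the groups called up to 19 lists.

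Replicate numbers are shared between the groups, and whether arrays of the same number deviate together from their group means was checked. For CR and Tg all 4 correlations were over 0.1 (0.353 to 0.649), so the fit with the number as a block is given beside that comparison; the pairing comes from the values, and the labels do not say what a number marks. No 2 arrays were duplicates: the highest correlation between arrays was 0.988. Other settings covered the normalization, the treatment and filtering of low values, the series matrix, the prior variance, the arrays in the fit, a replicate block, a fold threshold and leaving out each array. Settings chosen after seeing the data were 2 marker scores of other tissues as covariates, scanner intensities recovered from the z-scores (normexp, quantile normalization, median polish), and leaving out CR3, CR4 and Tg1 together. Depth is not defined for arrays, and their number limits the precision.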

Results

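Gene expression was measured in epididymal white adipose tissue, the fat pad along the epididymis, of rats aged 24 weeks. 4 arrays came from Wistar rats fed ad libitum (AL), 4 from Wistar rats given 70% of that energy from 6 weeks of age (CR), and 4 from heterozygous rats with an antisense transgene against growth hormone (GH), also fed ad libitum (Tg). Food was offered shortly before the dark phase, and tissue was taken after the lights came on the next morning. The median probe intensity recovered from the files ranged from 116 to 158 scanner units. The background was 34.5 to 44.1 on 11 arrays and 58.5 on CR3. Across the 23281 probe sets tested, the median SE of a log2 fold change was 0.11.

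The series design names principal component analysis as the way the 3 groups were compared. The first 2 components, with 47.4% and 23.0% of the variance, spread arrays of the same group apart and followed transcripts of tissues next to the fat pad. Protamine Prm1, a sperm chromatin gene, reached 13.82 (log2 signal) on AL2, 13.61 on Tg2, 13.25 on AL1 and 11.87 on CR1, against 4.94 on Tg1. The epithelial adhesion gene Epcam ranged from 4.26 on CR1 to 10.79 on Tg4. The third component, with 10.5% of the variance, ran from -32.68 to -16.13 in CR and from -1.46 to 20.26 in AL and Tg.

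Markers of other tissues were summarised as mean log2 signals of gene sets written after the levels of their genes had been seen. The spermatid score was 11.32 on AL2, 10.43 on Tg2, 10.05 on AL1 and 8.84 on CR1, and between 4.93 and 6.22 on the other arrays. The duct epithelium score was 10.60 on Tg4, 10.36 on Tg2, 10.32 on CR2, 10.17 on CR4, 9.91 on AL3 and 7.90 on Tg3, and at most 5.94 elsewhere. Caput epididymis transcripts stood at 11.97 on CR4 alone, and digestive enzymes of the exocrine pancreas at 11.04 on Tg1 alone. The kidney score stayed between 4.95 and 5.79. The epididymis and testis list fixed in advance had 9 members tested and 0 past the threshold in any comparison; Adam7, a caput epididymis gene, was 12.25 on CR4.

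**Figure D1:**
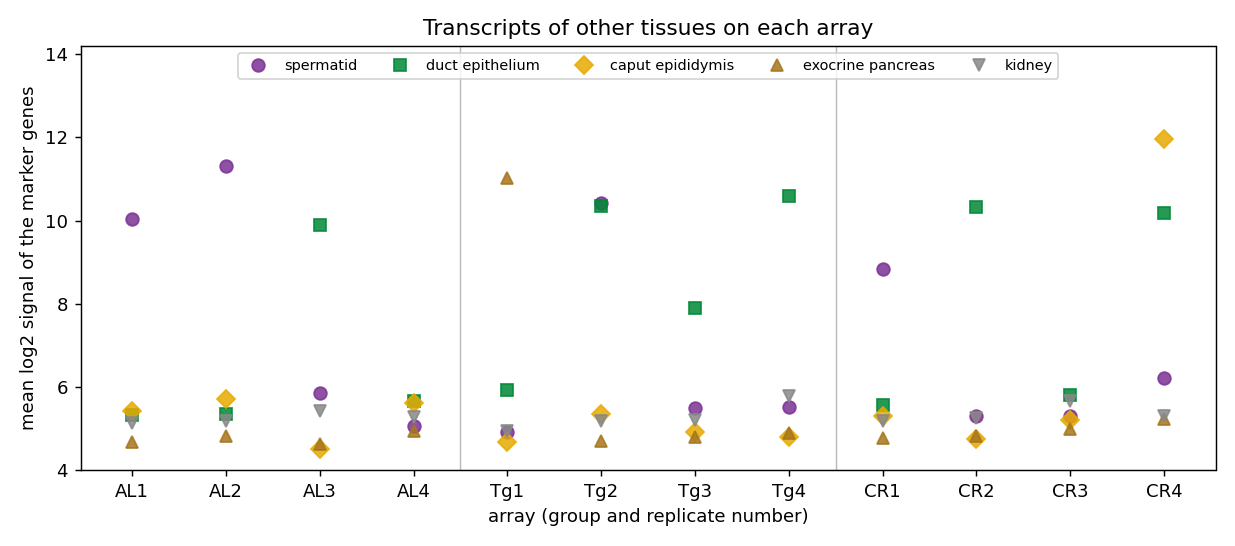
Mean log2 signal of 5 sets of marker genes (y axis) on each of the 12 arrays (x axis), 1 point per set and array. Spermatid and duct epithelium scores vary within every group, the caput epididymis score is high on CR4 (11.97) and the exocrine pancreas score on Tg1 (11.04).

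Group membership accounted for 20.7% of the squared distance between the 12 arrays (pseudo-F 1.18). In the exact permutation test 1830 of all possible partitions separated the arrays as well or better, p = 0.317. For the pairs of groups the exact permutation p was 0.2 for CR and AL, 0.343 for Tg and AL, and 0.486 for CR and Tg, where 35 splits allow no p under 0.0286. In this test, which takes the arrays as unpaired, the arrays as a whole did not separate by group beyond their spread. It leaves out that CR and Tg arrays of the same number deviated together.

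**Figure D2:**
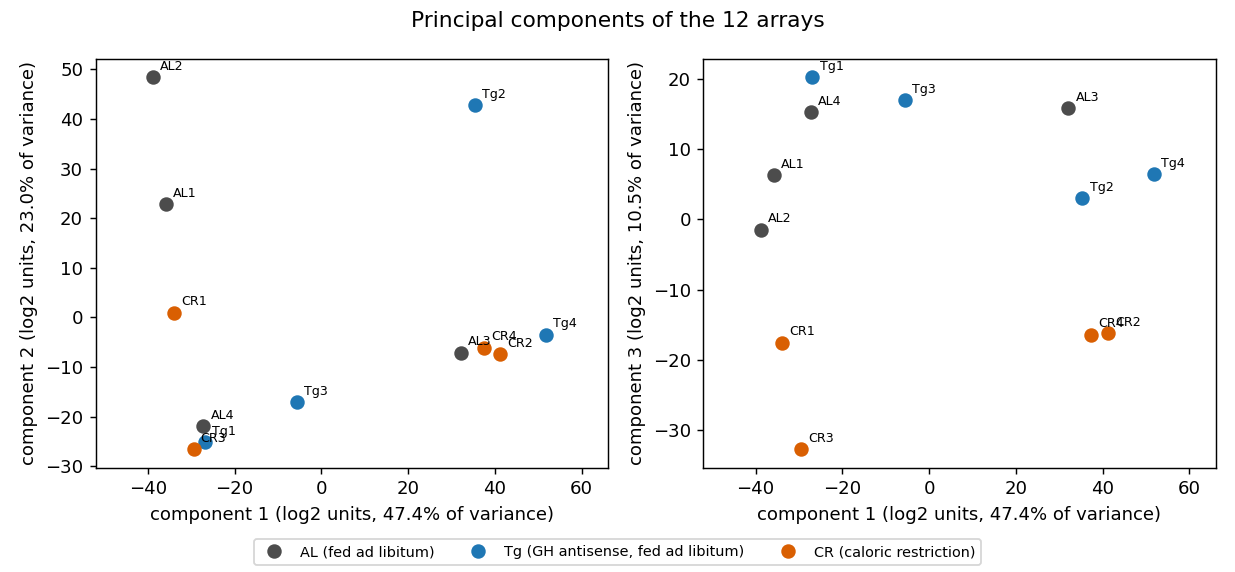
Scores of the 12 arrays on components 1 and 2 (left) and 1 and 3 (right), in log2 units, with colours for the groups and a label for each array. AL and Tg arrays lie among the CR arrays on components 1 and 2, and the 4 CR arrays lie lowest on component 3 (-16.13 and below).

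The comparison of CR with AL asks what restriction from 6 weeks of age changed in the fat of wild-type rats. Genes that make fatty acids rose together. Fasn, fatty acid synthase, rose 3.87-fold, from 11.05 ± 0.18 to 13 ± 0.29 (SD, n = 4; log2 fold change 1.95, SE 0.14, adjusted p = 0.000211). Acaca, which makes malonyl-CoA, rose 4.96-fold, Acly, which makes cytosolic acetyl-CoA from citrate, 4.33-fold, and Me1, a source of NADPH, 4.41-fold. The elongase Elovl6 rose 8.26-fold, from 6.92 ± 0.20 to 9.96 ± 1.10 (SD, n = 4; adjusted p = 0.0109), and the lipid droplet gene Pnpla3 rose 6.96-fold (adjusted p = 0.0106).

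Of the 18 members of the lipogenesis list tested, 14 rose, 0 fell, and all 18 were higher in CR, with a median log2 change of 1.27; adjusted over the list alone, 17 rose. The list was called at adjusted p = 3.22e-24 with the preset correlation and kept its call at adjusted p = 0.021 with an estimated correlation. Among its regulators, Srebf1 rose 1.55-fold at the edge of the threshold (adjusted p = 0.049; the call was lost in 20 of 26 alternatives). The desaturase Scd was 6.91-fold higher without passing the test (log2 fold change 2.79, SE 0.72, adjusted p = 0.0788). On CR1 and CR2 Scd lay above the deposited saturation level of the array, so the fold may be understated. Its AL3 value of 12.76 lay above the 9.17 to 10.66 of the other AL arrays, and without AL3 Scd passed (adjusted p = 0.0325). CR4, which carried caput epididymis transcripts, had the lowest CR value of Elovl6 (8.43, against 9.93 to 10.90) and of Me1 (9.79, against 11.23 to 11.95).

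**Figure D3:**
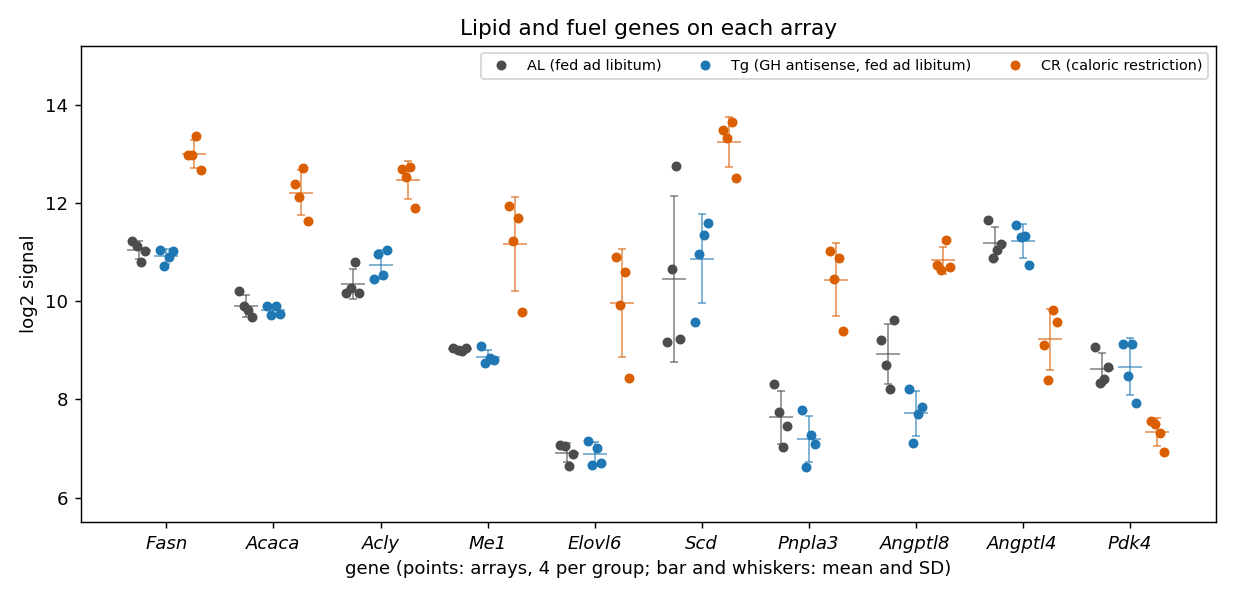
Log2 signal (y axis) of 10 lipid and fuel genes on each array, with 4 points per group and the group mean and SD as a bar with whiskers. The 4 CR values of Fasn lie above every AL and Tg value, those of Angptl4 and Pdk4 lie below, and Scd spreads widely in AL.

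Cholesterol synthesis genes were also higher in CR. Of 20 members tested, 19 were higher and 5 rose, with a median log2 change of 0.54; 16 rose adjusted over the list alone. Nsdhl rose 2.02-fold, Acat2 1.72-fold, Idi1 1.60-fold and Msmo1 1.44-fold. The list was called at adjusted p = 3.50e-13, and at adjusted p = 0.021 with an estimated correlation. Lipogenesis and cholesterol synthesis were the lists whose calls held with an estimated correlation in this comparison, 2 of the 10 called.

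The insulin-responsive glucose transporter Slc2a4 rose 2.26-fold (adjusted p = 0.0226) and hexokinase Hk2 2.09-fold (adjusted p = 0.0343). The pyruvate dehydrogenase subunits Pdhb and Pdha1 rose 2.23-fold and 1.66-fold, and the phosphatase gene Pdp2, whose product activates the enzyme, 1.61-fold. Pdk4, a kinase that inactivates it, fell by 1.29 on the log2 scale (adjusted p = 0.0388; the call was lost in 11 of 26 alternatives). Of the other kinase genes, Pdk1 was at 0.95 (adjusted p = 0.0512), with another of its probe sets up by 0.81 (adjusted p = 0.0451), Pdk2 at 0.45 (adjusted p = 0.175) and Pdk3 at 0.25 (adjusted p = 0.835). Pdk1, Pdk2 and Pdk3 were added to this comparison after their values were seen. Cpt1a, which brings fatty acids into mitochondria, fell by 0.78 (adjusted p = 0.0307), while Hadh of beta-oxidation rose 1.25-fold.

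The citrate cycle and pyruvate list had 4 members that rose and 1 that fell of 21 tested (10 and 1 adjusted over the list alone; median 0.27), among them malate dehydrogenase Mdh1, up 1.37-fold. Of 28 oxidative phosphorylation genes, 27 were higher, 2 rose (Cyc1 1.28-fold, Ndufs3 1.27-fold) and 11 rose adjusted over the list alone (median 0.22). Glycolysis had 2 of 18 that rose (Aldoa 1.29-fold and Hk2) and 4 adjusted over the list alone. The thermogenic list had 0 of 11 past the threshold, also adjusted over the list alone, with Ppargc1a at 0.83 (adjusted p = 0.238) and Esrra at 0.30; Ucp1 was 4.83 in AL and CR and was left out as dim. All 4 lists were called up with the preset correlation. With an estimated correlation the adjusted p was 0.267 for the citrate cycle and for oxidative phosphorylation, 0.111 for glycolysis and 0.174 for the thermogenic list, which also lost its call in 10 of 27 alternatives.

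Secreted regulators of lipoprotein lipase moved in opposite directions. Angptl8, raised by feeding, rose 3.74-fold (adjusted p = 0.016), and Angptl4, raised by fasting, fell by 1.96 on the log2 scale, from 11.19 ± 0.33 to 9.22 ± 0.63 (SD, n = 4; adjusted p = 0.0145). Gpam, which starts glycerolipid synthesis, rose 3.44-fold, and was the 1 of 20 triglyceride synthesis and storage genes past the threshold (1 adjusted over the list alone; list adjusted p = 0.425). Leptin (Lep, 0.04, SE 0.13) and adiponectin (Adipoq, 0.02, SE 0.09) differed by less than their spread. On the reported scale Adipoq lay above the deposited saturation level on AL4 and CR2, so a difference in Adipoq could be hidden. The adipokine list had Angptl4 alone past the threshold of 15 members, the adipocyte identity list Slc2a4 alone of 16, and the lipolysis list 0 of 13. Adjusted over the list alone, 3 adipokines rose and 3 fell, 1 adipocyte identity gene rose and 1 fell, and 0 lipolysis genes passed. Their list adjusted p were 0.974, 0.532 and 0.60. Pparg was at 0.38 (adjusted p = 0.55).

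Macrophage genes were lower in CR. All 26 members tested were lower, 8 of them past the threshold and 17 adjusted over the list alone, with a median log2 change of -0.53. Osteopontin Spp1 fell by 1.14, Ptprc, the pan-leukocyte antigen, by 0.79, Adgre1 (the F4/80 antigen) by 0.68, Cybb, a subunit of the phagocyte oxidase, by 0.64 and Cd68 by 0.59 (adjusted p from 0.0106 to 0.0461). The chemokine Ccl2 was at -0.81 without passing (adjusted p = 0.176). The list was called at adjusted p = 1.83e-14, but adjusted p = 0.0864 with an estimated correlation.

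Other stromal and stress lists were called down with the preset correlation. Among 26 fibroblast and matrix genes, 24 were lower, Lum fell by 0.50 and Sparc by 0.39, and 9 fell adjusted over the list alone (median -0.29; adjusted p = 0.267 with an estimated correlation). Of 16 endothelial genes 15 were lower, 0 past the threshold and 3 adjusted over the list alone, with Tie1 at -0.40 and Eng at -0.38 (median -0.35; adjusted p = 0.48 with an estimated correlation). Immediate early genes had 3 of 19 that fell, Jun by 0.79, Atf3 by 0.55 and Klf6 by 0.52, and 8 adjusted over the list alone (median -0.39; adjusted p = 0.267 with an estimated correlation). Spermatid scores, at 10.05 and 11.32 on AL1 and AL2 and 8.84 on CR1, and duct epithelium scores, high on AL3, CR2 and CR4, varied within both groups beside these lists.

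In the GH and IGF-1 axis, 24 genes were tested and Igfbp5, a binding protein of IGF-1, fell by 0.55 (adjusted p = 0.0285; 2 fell adjusted over the list alone; list adjusted p = 0.697). Igf1 was at -0.39 on its brightest probe set (SE 0.11, adjusted p = 0.0908), and another of its probe sets fell by 0.70 (SE 0.15, adjusted p = 0.0462). The brightest probe set passed with quantile normalization (-0.43, adjusted p = 0.024). It also passed with recovered scanner intensities (-0.43, adjusted p = 0.0278), a setting chosen after seeing the data. Ghr was at -0.32 (adjusted p = 0.27), Socs2 at -0.20 (adjusted p = 0.609) and Gh1 at 0.21 (adjusted p = 0.245).

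Further genes with large changes fell outside the lists. C8h11orf54 rose 3.11-fold and Parm1 2.65-fold. Grb14, an adaptor that restrains insulin receptor signalling, fell by 1.40, from 9.58 ± 0.21 to 8.18 ± 0.07 (SD, n = 4; adjusted p = 0.00195). The sialic acid receptor gene Siglec10 fell by 1.46, Kcnip1 by 1.09, the imprinted transcription factor gene Plagl1 by 1.03, the secreted phospholipase gene Pla2g2d by 1.0, Chrna1 by 0.92, Rbp7, which encodes a retinol carrier, by 0.92 and the chemokine gene Ccl9 by 0.90. With the series matrix Plagl1 was at -0.26 (adjusted p = 0.386).

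In the remaining lists the preset test made no call. Fatty acid oxidation had Hadh and Cpt1a past the threshold of 21 (adjusted p = 0.217), and glucocorticoid and fasting response had Pdk4 and Angptl4 of 14 (0.165). With 0 members past the threshold, list adjusted p was 0.0887 for MHC class II (Ciita -0.42, RT1-Db1 -0.62), 0.214 for lymphocyte (Cd4 -0.45, Il7r -0.43), 0.319 for interferon response and 0.0751 for blood and red cell (Pf4 -0.46). It was 0.96 for smooth muscle and pericyte, 0.731 for skeletal muscle, 0.401 for epididymis and testis, 0.401 for mesothelium and epithelium, and 0.697 for nerve and Schwann cell. It was 0.907 for clock (Bhlhe40 at 1.0, adjusted p = 0.0714), 0.217 for antioxidant and metallothionein (Prdx6 0.51, Prdx4 -0.26), 0.153 for ER chaperones and 0.117 for proliferation (Mki67 -0.74, Cdk1 -0.68). Adjusted over the list alone, 2 fatty acid oxidation genes rose and 2 fell, 3 glucocorticoid response genes fell, 2 blood genes fell, 1 MHC class II gene fell, 1 clock gene rose, and 1 antioxidant gene rose and 1 fell.

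In all, limma called 417 probe sets between CR and AL, 202 up (149 gene symbols) and 215 down (166), with 67 unnamed or with several genes; 163 differed at least 1.5-fold. At unadjusted p under 0.05 there were 3973. The arrays of the groups did not overlap for 415 of the 417 and for 10.2% of all probe sets tested, against 2.86% by chance. That chance share is an average over splits. Probe sets vary together and its spread was not computed, so the values do not show an excess. With the spermatid and duct epithelium scores as covariates, chosen after seeing the data, 1648 were called (801 up, 847 down), among them all 417, and Igf1 passed (adjusted p = 0.0236). The count fell to 256 without Tg2, 164 without CR1, 147 without AL1, 116 without CR2, 116 without CR3, 106 without AL3 and 43 without AL4, to 110 without CR3, CR4 and Tg1, and to 88 with the 8 arrays of the groups alone. Fasn, Acaca, Acly, Elovl6, Pnpla3, C8h11orf54, Siglec10, Grb14, Pdhb and Jun kept their calls in all 26 alternatives. Gpam (adjusted p = 0.0552) and Angptl4 (0.0549) lost theirs without AL4, and Angptl8 (0.111) and Pla2g2d (0.0665) without CR3, CR4 and Tg1. Of the other members named as past the threshold, the call was lost in 15 or more alternatives for Hadh, Cyc1, Spp1, Cybb, Lum and Klf6, in 10 to 14 for Idi1, Mdh1, Hk2, Igfbp5, Chrna1 and Rbp7, and in 1 to 9 for the rest. Fitted with the marker scores, the lists of triglyceride synthesis and storage (adjusted p = 0.0198), adipocyte identity (0.0146), fatty acid oxidation (0.00694) and MHC class II (0.000235) were called too, at the preset correlation. Without the scores their adjusted p was 0.873, 0.873, 0.809 and 0.765 with an estimated correlation, which was not run with the scores.

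The comparison of Tg with AL asks what the antisense transgene against GH changed in rats that ate freely. Little passed the test. Spn, which encodes the leukocyte surface protein sialophorin, fell by 0.50 on the log2 scale, from 8.39 ± 0.07 to 7.89 ± 0.03 (SD, n = 4; SE 0.06, 1.41-fold, adjusted p = 0.0411). One probe set of the actin regulator Diaph1 fell by 0.86 (adjusted p = 0.0436), while the brightest Diaph1 probe set was at -0.04; Diaph1 lies outside the rule and was chosen after its values were seen. Spn lost its call in 18 of 26 alternatives. It was lower in CR too, by 0.45 (adjusted p = 0.00854).

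The genes of the GH axis did not pass. Gh1, whose messenger the transgene is directed against and which is made in the pituitary, was 5.55 ± 0.05 in AL and 5.60 ± 0.16 in Tg (SD, n = 4), so fat tissue does not check the transgene. The genotype field of the labels gives the Tg arrays the entry of rats without it, so the group rests on titles and source names. Ghr was at -0.40 (SE 0.14, adjusted p = 0.68), Igf1 at -0.20 (SE 0.11, adjusted p = 0.84), Socs2 at -0.02 and Foxo1 at -0.27. Leptin was at -0.36 (SE 0.13, adjusted p = 0.708). Of genes of fatty acid synthesis, Fasn was at -0.12 (SE 0.14), Acly at 0.40 (SE 0.21), Scd at 0.41 (SE 0.72) and Srebf1 at -0.23 (SE 0.14).

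With the preset correlation 10 of the 30 lists were called in Tg, and 0 held with an estimated correlation. Lower were lipolysis (median -0.16, with G0s2 at -0.51 and Mgll at -0.49), endothelial (-0.21, all 16 lower, Pecam1 -0.45), macrophage (-0.16, Spp1 -0.71), adipokines (-0.12, Fgf21 -0.38), lymphocyte (-0.19), and immediate early genes (-0.31, 18 of 19 lower, Atf3 -0.34, Jun -0.30). Also lower were adipocyte identity (-0.13, Acp5 -0.47), triglyceride synthesis and storage (-0.12, Gpd1 -0.28, Cidec -0.17) and oxidative phosphorylation (-0.05, Ndufv2 -0.18). With an estimated correlation the adjusted p was 0.719 for lipolysis, endothelial, macrophage and adipokines, 0.708 for lymphocyte and immediate early, 0.815 for adipocyte identity, and 0.854 for the other 2. Mesothelium and epithelium genes were higher (median 0.38, Krt19 1.77, Gpm6a 0.58; adjusted p = 0.719 with an estimated correlation). Of all 30 lists, 0 members passed the threshold; adjusted over the list alone, 2 immediate early genes and 1 lipolysis gene fell.

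Beside the epithelial list, the duct epithelium score was 10.60 on Tg4, 10.36 on Tg2 and 7.90 on Tg3, and high on AL3 alone among the AL arrays. The list kept its call with the marker scores as covariates (adjusted p = 0.0176) and lost it without Tg1 (0.0913) and without CR3, CR4 and Tg1 (0.0696). With the marker scores as covariates, triglyceride synthesis and storage (adjusted p = 0.683) and oxidative phosphorylation (adjusted p = 0.636) turned upward and lost their calls, and the citrate cycle list turned upward (adjusted p = 0.0125). Lipolysis (adjusted p = 0.622), adipocyte identity (0.765) and adipokines (0.172) lost their calls, and glycolysis (0.0427) and MHC class II (1.18e-08) gained one at the preset correlation. Without the scores, these 2 lists were at adjusted p = 0.815 and 0.854 with an estimated correlation. The lists not called in the reported values ranged in adjusted p from 0.272 for glycolysis to 0.909 for lipogenesis.

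In all, limma called 2 probe sets between Tg and AL, 0 up and 2 down, against 1358 at unadjusted p under 0.05 (581 up, 777 down). With no effect, a share of 0.05 of the 23281 probe sets tested would lie there on average. The 1358 are therefore not read as a response to the transgene. The groups did not overlap for 4.37% of the probe sets tested, against an average of 2.86% by chance, whose spread was not computed. The count was 0 without any one of the arrays Tg1 to Tg4, AL2 to AL4 or CR1 to CR3, 1 without AL1 (a probe set that rose and is neither of the 2), and 0 with quantile normalization, the series matrix or the recovered scanner intensities; with the marker scores it was 1.

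The direct comparison of CR with Tg asks where restricted and transgenic rats differed. The fatty acid synthesis genes that separated CR from AL separated it from Tg. Pnpla3 was 9.44-fold higher in CR (log2 fold change 3.24, SE 0.38, adjusted p = 0.00501), Angptl8 8.67-fold (10.83 ± 0.28 against 7.72 ± 0.46, SD, n = 4; adjusted p = 0.00168), Elovl6 8.43-fold, Acaca 5.27-fold, Me1 4.91-fold and Fasn 4.22-fold (adjusted p = 0.000108). Angptl4 was 4.01-fold lower in CR (adjusted p = 0.0143), and log2 changes were -1.37 for Plagl1, -1.35 for the lectin gene Cd209f, -1.34 for Pdk4 and -1.26 for Siglec10.

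Of 18 lipogenesis genes 14 were higher past the threshold and 17 adjusted over the list alone, with a median of 1.23; Acly was 3.29-fold and Srebf1 1.81-fold higher, and Scd did not pass (2.37, adjusted p = 0.124). Of 20 cholesterol synthesis genes 8 passed and 15 adjusted over the list alone (median 0.50), among them Nsdhl (2.05-fold), Dhcr7 (1.95-fold), Fdps (1.88-fold) and Cyp51 (1.80-fold). These 2 lists kept their calls with an estimated correlation, both at adjusted p = 0.0136, and were the only ones of the 13 called that did.

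Higher in CR with the preset correlation were 8 further lists. Oxidative phosphorylation had all 28 genes higher, 4 past the threshold and 23 adjusted over the list alone (Cyc1 1.33-fold, Ndufs3 1.29-fold, Atp5pb 1.26-fold, Atp5po 1.21-fold; adjusted p = 0.192 with an estimated correlation). The citrate cycle and pyruvate list had 6 up and 1 down, and 11 and 1 adjusted over the list alone (Pdhb 2.30-fold, Pdk1 2.19-fold, Pdha1 1.63-fold, Pdp2 1.48-fold; adjusted p = 0.231 with an estimated correlation). Glycolysis had 3 of 18 up and 5 adjusted over the list alone (Hk2 2.47-fold, Aldoa 1.43-fold, Pgam1 1.26-fold; adjusted p = 0.0543 with an estimated correlation). Triglyceride synthesis had Gpam (3.14-fold) and Gpd1 (1.58-fold), lipolysis G0s2 (1.53-fold), and adipocyte identity Slc2a4 (2.40-fold). With an estimated correlation their adjusted p was 0.64, 0.59 and 0.635, against 0.64 for adipokines and 0.705 for ER chaperones (Pdia4 at 0.45, adjusted p = 0.0599). At the preset correlation, the ER chaperone list lost its call without CR4, which carried caput epididymis transcripts (camera adjusted p = 0.751). It also lost it without CR3, CR4 and Tg1 (0.927), without Tg4 (0.0541), with the series matrix (0.0903) and without the dim filter (0.0531). Adjusted over the list alone, 5 triglyceride genes rose and 1 fell, 3 lipolysis genes, 1 adipocyte identity gene and 2 ER chaperones rose, and 5 adipokines rose and 1 fell.

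Lower in CR were 3 lists. Macrophage genes were lower for 25 of 26, with Cybb at -0.68, Adgre1 at -0.53 and Csf1r at -0.45 past the threshold and 10 adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). Fibroblast and matrix genes had Mmp2 at -0.51 and Col6a3 at -0.45 past it and 5 adjusted over the list alone (adjusted p = 0.265 with an estimated correlation). The glucocorticoid and fasting response list had Angptl4, Pdk4 and Txnip (-0.46) of 14, also adjusted over the list alone (adjusted p = 0.191 with an estimated correlation; 0.0853 with the marker scores as covariates). Outside these lists, Jun of the immediate early list (-0.49, adjusted p = 0.0189) and Cpt1a of the fatty acid oxidation list (-0.80, adjusted p = 0.0307) passed. Igf1 (-0.19), Ghr (0.09), Lep (0.40, adjusted p = 0.136), Adipoq (0.05), Pparg (0.44), Ppargc1a (0.23), Cd68 (-0.36, adjusted p = 0.0683) and Ccl2 (-0.48) did not.

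**Figure D4:**
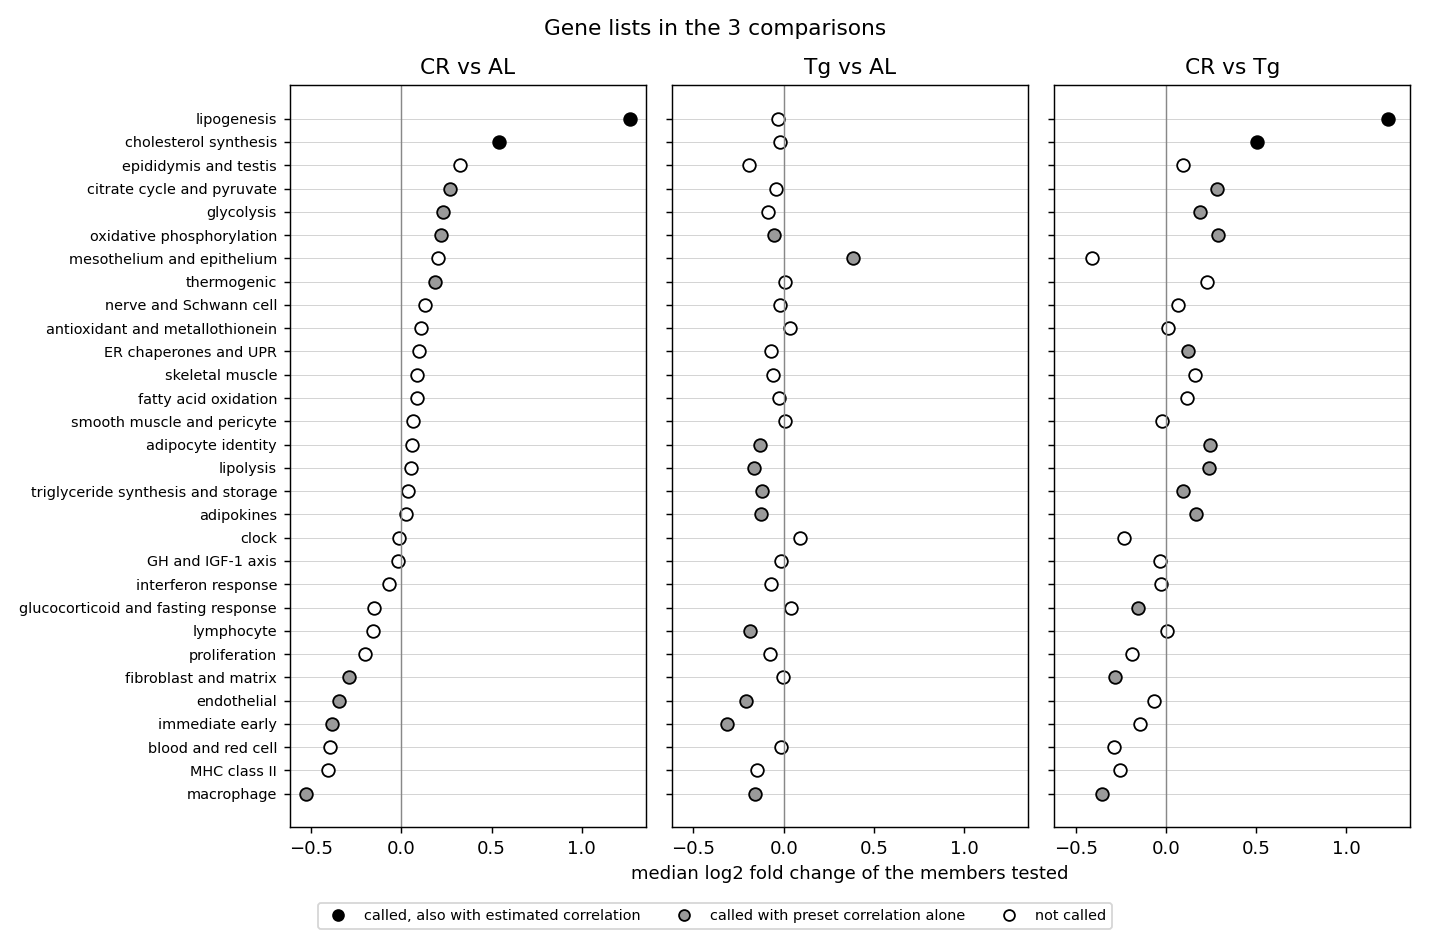
Median log2 fold change (x axis) of the tested members of each of the 30 gene lists (y axis) in the 3 comparisons, with filled points for calls that hold with an estimated correlation, grey for calls with the preset correlation alone and open for none. Lipogenesis (1.27 and 1.23) and cholesterol synthesis (0.54 and 0.50) are filled for CR against AL and against Tg, and 0 lists are filled for Tg against AL.

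In all, 386 probe sets were called between CR and Tg, 246 up (176 symbols) and 140 down (100), with 4163 at unadjusted p under 0.05; 150 differed at least 1.5-fold. The groups did not overlap for 12.1% of the probe sets tested, against an average of 2.86% by chance, whose spread was not computed. Of the calls, 142 were up and 70 were down both against Tg and against AL, and 0 were opposite. Independent lists would share 2.13 and 1.29, but both comparisons use the 4 CR arrays, which alone favours the same direction. Over all probe sets tested, the signs were the same for 75.0%, against 66.6% in simulations with no effect. The simulations draw every probe set independently, so they cannot tell whether that difference lies beyond chance. With the marker scores as covariates 1466 were called (725 up, 741 down), among them all 386. The count was 567 without CR4 and fell to 34 without CR1, 38 without Tg2, 67 without Tg3, 74 without CR3, 125 without Tg1, 132 without CR2, 141 without Tg4, 186 without AL1 and 229 without AL4. It was 97 without CR3, CR4 and Tg1, 22 with the 8 arrays of the groups alone and 221 with each array centred on its median. Pnpla3, Angptl8, Acaca, Plagl1, Fasn and Acly kept their calls in all 26 alternatives, while Csf1r lost its call in 21, Atp5po in 20, Dhcr7 and Txnip in 17 each, and Cd209f and Gpd1 in 15 each. The adipokine and the glucocorticoid response lists lost theirs in 11 of 27 each; with the marker scores as covariates adipokines were at adjusted p = 0.065, and the thermogenic (0.00488) and blood (0.0481) lists were called, at the preset correlation. Without the scores, the thermogenic and blood lists were at adjusted p = 0.192 and 0.262 with an estimated correlation.

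CR and Tg arrays of the same replicate number deviated together, so a fit with the number as a block stands beside this comparison. In both groups, arrays 2 and 4 had duct epithelium scores of 10.17 to 10.60, and arrays 1 and 3 scores of 5.56 to 7.90. The common deviation cannot be told apart from that tissue RNA, and only 2 of the 4 CR arrays matched their own number best. The fit with the block called 196 probe sets. Past the threshold without the block but not with it were Cd209f (adjusted p = 0.0739 with the block), Dhcr7 (0.0612), Cyp51 (0.0612), Gpd1 (0.0598), Cpt1a (0.0703), Atp5pb (0.0612) and Atp5po (0.0922). The same held for Pdp2 (0.0817), Pgam1 (0.051), Cybb (0.0635), Adgre1 (0.0582), Csf1r (0.0957), Col6a3 (0.0829) and Txnip (0.0817). The platelet gene Pf4 passed with the block alone (0.0399), as did, at the preset correlation, the lists of fatty acid oxidation (0.0337), thermogenic (0.0402) and blood and red cell genes (0.0461). Without the block their adjusted p was 0.705, 0.192 and 0.262 with an estimated correlation, which was not run with the block.

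Whether CR and Tg shared changes was read against their common AL arrays. The log2 fold changes of CR and of Tg against AL correlated at r = 0.601 across probe sets, which are not independent replicates. Simulated groups with no effect gave a mean r of 0.501 and at most 0.545 against the same controls. They draw every array and every probe set independently. They leave out that CR and Tg arrays of the same number deviate together, and that probe sets vary together. The simulated values therefore spread too little to tell whether an r of 0.601 lies beyond chance. The covariance was 0.0430 against 0.0240 simulated, a difference of 0.0190. With the AL arrays split between the comparisons, r lay between -0.104 and 0.467 (mean 0.194). Both changes had the same sign for 61.6% of probe sets, against 66.7% in the simulations. Calls overlapped for 1 probe set, that of Spn, down in both, where independent lists would share 0.0185, a value that leaves out the common AL arrays. The simulations gave 0, but hold no effects that could be called. Without CR2 r was 0.401, without CR4 0.426 and without AL3 0.770, and with the marker scores as covariates it was 0.402.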

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

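The tests of degradation, background and tissue RNA on the components were chosen only after the result was seen. An array was singled out where its gap to the nearest of the other 3 in its group, as a share of the group's range, exceeded the 95% limit of Dixon's test for 4 values. Chance does this in about 1 in 20 groups; here it was 23 of 330.

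Among the scores of other tissues, 4 arrays stood apart. They were Tg2 for spermatid (10.43, against 4.93 to 5.52), AL3 for duct epithelium (9.91, against 5.33 to 5.67), CR4 for caput epididymis (11.97, against 4.76 to 5.30) and Tg1 for exocrine pancreas (11.04, against 4.69 to 4.89). AL3 was highest of AL on component 1 (32.1, against -38.77 to -27.21), and CR3 lowest of CR on component 3 (-32.68, against -17.54 to -16.13).

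Among the named genes, 17 values stood apart. On CR4, Adam7 was highest (12.25), Siglec10 highest (6.45) and Gh1 lowest (5.66). On CR3, Angptl8 (11.25) and Pgam1 (11.85) were highest; on CR1, Ghr was highest (11.56) and Cd4 lowest (7.32); on CR2, Col6a3 was lowest (10.18). On AL3, Prdx6 was highest (10.23) and Kcnip1 lowest (7.17), on AL4 Col6a3 was highest (10.95), and on AL2 Mki67 (7.18). Of the Tg arrays, Tg1 was lowest for Aldoa (12.23) and Ndufs3 (9.71), Tg2 highest for Pdia4 (8.99), Tg3 highest for Csf1r (9.94) and Tg4 lowest for Adipoq (13.20).

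Arrays of the same group lay far apart on the first 2 components. The first test of tissue RNA used the marker scores (97.5%), which had been written with the components in view; it was replaced, after that value was seen, by the epididymis and testis list fixed in advance. With the genes of all these sets left out of the components, the first 3 components of that list explained 95.2% of the spread within groups (permutation p = 0.0002, shuffled mean 32.7%). Array background explained 22.5% (permutation p = 0.0876), under the 25% set for it. The slope along the probes explained 34.7% (permutation p = 0.0262, shuffled mean 10.7%). It was taken as a measure of RNA degradation, which assumes that the deposited probe order runs along the transcript. That order was not checked. That transcripts of duct and testis differ between arrays is seen in their levels, such as Prm1 from 4.94 on Tg1 to 13.82 on AL2. They explained more of the spread than the slope did, with 3 covariates against 1. The 2 were not fitted together, so RNA degradation stays open as a further source, and no biological explanation was tested.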

How the results depend on the processing

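The covariates, the recovered scanner intensities and the joint removal of 3 arrays were chosen after seeing the data. Adding 16 to the signal, setting signals under 32 to 32, testing without the dim filter, and a prior variance without trend or robust left the 3 counts of probe sets within 1.5 times of those reported. Where a count or list moved, the cause was not tested, unless fewer arrays or a stricter threshold were used.

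With the correlation estimated per list, 2 lists were called for CR against AL, 0 for Tg against AL and 2 for CR against Tg. At least 1.5-fold were 163, 1 and 150 probe sets, with an overlap of 0 between CR and Tg. Counts for Tg against AL were 0 with quantile normalization, with each array centred on its median, with the series matrix and with recovered scanner intensities, each with an overlap of 0. Median centring gave 305 for CR against AL and 221 for CR against Tg, and testing only above the median signal gave 1 for Tg against AL. In limma, the reported Tg comparison had 1358 probe sets at unadjusted p under 0.05, where a share of 0.05 of those tested is the average with no effect. With the 8 arrays of each comparison alone, 88, 0 and 22 were called (overlap 0).

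With the replicate number as a block, 264, 0 and 196 were called (overlap 0). CR and AL arrays of the same number correlated at -0.530 to 0.529 and Tg and AL arrays at -0.336 to 0.467, 1 of 4 best with its own number in each, so they share only a number. For CR against Tg all 4 pairs correlated above 0.1, 2 of them best; the block changed no call of a named gene or list there beyond those in the report. With the marker scores as covariates, 1648, 1 and 1466 were called and r between the changes was 0.402. In Tg against AL, that setting reversed triglyceride synthesis and storage (adjusted p = 0.683), oxidative phosphorylation (adjusted p = 0.636) and the citrate cycle and pyruvate list (adjusted p = 0.0125). Without CR3, CR4 and Tg1 together, 110, 0 and 97 were called (overlap 0).

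Leaving out each array in turn gave 43 to 390 probe sets for CR against AL, 0 to 2 for Tg against AL and 34 to 567 for CR against Tg. Lists called ranged from 9 to 14, 7 to 11 and 8 to 14, the overlap from 0 to 1, and r from 0.401 to 0.770. The share of distance between groups ranged from 17.8% to 29.7%. A robust prior was not run for the lists, and a fit with the working session was not run, since the only such code in the labels is 1 per group and cannot be separated from the groups. Dim genes are limited by the background, 58.5 on CR3 and 34.5 to 44.1 elsewhere, against median intensities of 116 to 158.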

Other observations

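The tests of adipocyte share and of stromal share, and the fits with the marker scores as covariates, were chosen only after the result was seen, as were the genes of the next 2 paragraphs.

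Single genes outside the fixed lists passed the threshold in CR. Ppp1r3b, which brings a phosphatase to glycogen, rose by 1.38 against AL (SE 0.23, adjusted p = 0.0191) and by 1.55 against Tg (adjusted p = 0.0143). Glycogen phosphorylase Pygl rose by 0.87 and 0.89 (adjusted p = 0.0148 and 0.0149), and the branching enzyme gene Gbe1 by 0.73 and 0.76 (adjusted p = 0.0224 and 0.021). The synthase genes Gys2 (0.95 against AL, adjusted p = 0.0822) and Gys1 (0.23, adjusted p = 0.249) did not pass.

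The pentose phosphate genes Tkt and Taldo1 rose by 1.07 and 0.60 against AL (adjusted p = 0.0191 and 0.0109). Mpc1, part of the mitochondrial pyruvate carrier, rose by 1.04 (adjusted p = 0.0145), and its partner Mpc2 was at 0.51 against AL (adjusted p = 0.0608) and rose by 0.64 against Tg (adjusted p = 0.03). The first enzymes of haem synthesis, Alas1 and Alad, rose by 0.79 each against AL (adjusted p = 0.0125 and 0.00377).

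The lipogenesis list was higher in CR than in AL. With the marker scores as covariates, the median of its members past the threshold was 1.5, against 1.35 without. This argues against the spermatid and duct epithelium RNA that the scores follow. Caput epididymis RNA, high on CR4, was not in that fit. Without the scores the adipocyte identity list had a median of 0.058, against 1.27 for lipogenesis. This argues against a larger share of adipocyte RNA as the main source. With the scores the adipocyte identity list was called up (camera, preset correlation, adjusted p = 0.0146) and Pparg passed (0.58, limma adjusted p = 0.0356). Some difference in adipocyte share therefore stays open. Without CR3 the lipogenesis median was 1.27, which argues against the array with the highest background. Restriction, the food given before the dark phase and a working session shared by each group stay open, as untested.

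The macrophage list was lower in CR than in AL, a call lost with an estimated correlation (adjusted p = 0.0864). With the marker scores as covariates its median was -0.60, and without CR3 -0.47. This argues against the spermatid and duct epithelium RNA that the scores follow, and against that array. The 5 stromal lists differed from one another over genes (permutation p = 1e-05, the smallest possible with 100000 shuffles). The shuffles take genes as independent, but members of a list vary together (estimated correlation from 0.070 for lymphocyte to 0.56 for endothelial genes). That p is therefore too small to decide on an equal loss of all stromal RNA. Taking arrays as the unit, the change of the macrophage list lay below those of the lymphocyte (-0.12), fibroblast (-0.26) and smooth muscle (0.02) lists (exact p = 0.0286 each, the smallest possible with 35 splits), but was not told apart from that of the endothelial list (-0.30, exact p = 0.343). These exact p-values were not adjusted for the number of lists compared. An equal loss of all stromal RNA, a lower share of macrophages and lower expression in each stay open.

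Other splits of the 8 arrays of each comparison, 35 with the real one, were fitted in the same way. For CR against AL the real split alone called as many probe sets (417 real, highest other 7), which argues against chance for the count. That is the smallest share 35 splits allow, and in the permutation test of distances these groups did not separate (exact p = 0.2). For Tg against AL chance is left open (1 split, 2 real, highest other 1), since the margin is 1 probe set and the real count was 0 in most alternatives. For CR against Tg it cannot be excluded (2 splits; 386 real, highest other 3127). That other split sets Tg1, Tg3, CR1 and CR3 (duct epithelium scores 5.94, 7.90, 5.56 and 5.80) against Tg2, Tg4, CR2 and CR4 (10.36, 10.60, 10.32 and 10.17), parts 0 of the 4 same-numbered pairs and points to a structure of the samples. It called 0 once the marker scores entered as covariates. That fall was built in, since the duct epithelium score, which separates the sides of this split, is among the covariates. Among the 8 splits that part all 4 pairs, too few for a share under 0.05, the real one called 386 and the highest other 0 in limma, where the real split had 4163 at unadjusted p under 0.05. For the lists called chance cannot be excluded: 18 splits called as many for CR against AL (10 real, highest other 18), 3 for Tg against AL (10 real, highest other 12) and 10 for CR against Tg (13 real, highest other 19). With the marker scores as covariates, chosen after the data were seen, 1 split called as many in each comparison. For CR against AL this again argues against chance (1648 real, highest other 9), but the scores can take up splits that compete with the real one. Chance is left open for Tg against AL (1 real, highest other 0). It is left open too for CR against Tg (1466 real, highest other 0), where the 8 splits that part the pairs are too few. There the scores also take up the split that had called 3127.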
